A study of Mus musculus with 8 samples.

How the data were processed

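RNA was measured in 8 samples, 2 each of L-GMPs and bulk GFP-positive cells from control and Dnmt1 fl/+ leukaemias. Per the labels' protocols and the series text, marrow progenitors were exposed to MLL-AF9 retrovirus for 2 days, sorted for GFP and given to recipients irradiated with 600 rad, which from 2 weeks later received 7 injections of poly(I:C) at 25 µg/kg. L-GMPs were sorted as lineage-negative, IL-7Ra-negative, c-Kit-positive, Sca-1-negative, FcγR-positive and CD34-positive cells. Also per the labels' protocols, RNA was amplified with a whole-transcript kit for small inputs, labelled with biotin and hybridised to Affymetrix mouse arrays.

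The deposited values are probe set intensity values on a linear scale, as made by the authors. The signal algorithm, the scaling target and detection calls are not given in the sources used here. The mean of each array without its top and bottom 2 percent lay between 769 and 842, so arrays were close in level but not equal, and between 291 and 327 values per array were exactly 1. The scale is taken as linear from the values. Between 17.8 and 19.9 percent of values per array lay below 16, and such dim values carry little information on direction.

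Of 22690 probe sets, 64 Affymetrix controls were left out. In the platform annotation, 20380 of the others had 1 gene, 691 several and 1555 none, and 20351 of the single-gene probe sets matched the gene table through their gene identifier, with 0 symbols updated. Values were quantile normalized between arrays and log2(value + 16) was taken. Each of 12393 genes was represented by its probe set of highest mean over the 8 arrays, and 4956 genes had more than 1 probe set. For genes named for their largest change or smallest p, no other probe set moved in the opposite direction at an unadjusted p under 0.05. This check covered the genotype and population comparisons, and it left out genes named for other reasons. The 2246 probe sets with several genes or none were tested on their own.

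All 8 arrays were fitted in 1 limma model (version 3.58.1, R 4.3.3) with a mean per group, lmFit and eBayes, with 4 residual degrees of freedom, and Benjamini-Hochberg adjustment within each of 5 comparisons. A gene was called at an adjusted p under 0.05. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Gene lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the 32 lists of a comparison. A list of 5 sex-linked genes, of which 4 were measured, served only as a check of the samples.

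The groups, the tests, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took, per comparison and direction, up to 12 genes of largest change past the threshold with no overlap between groups and the higher group above the median gene, filled up to 6 with genes of smallest unadjusted p under 0.01 that met the other conditions. Predicted genes and clones were not named. It added up to 4 members of smallest p per list of at least 5 measured genes and fixed genes of methylation, Hox, stem, lineage, cell cycle inhibitor and Polycomb function. The text names a selection of the genes this rule allows, and that selection was made after their values were seen. The genes outside it were Ica1, Siglecf, Mcpt8, Lipg and Tanc1 in L-GMPs, and those compared between single leukaemias. Ica1 misses the rule because its bulk control level lies below that of the median gene.

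Per the labels, control and experimental samples of a replicate number were littermates, so the number pairs the genotypes. The differences between numbers 1 and 2 correlated across genes at 0.09 between control and Dnmt1 fl/+ L-GMPs and at 0.10 between the bulk groups. Between L-GMPs and bulk cells the correlation was 0.80 within Dnmt1 fl/+ and 0.14 within controls. Of 4 hybridisation control transcripts, 3 split by number, with mean signals on arrays numbered 1 and 2 of 4386 and 2631 for bioB, 6395 and 4076 for bioC, and 15414 and 11852 for bioD. The fourth, cre, did not split (27194 and 28031). Number may thus mark a batch that holds all 4 groups. It was not part of the main fit and entered as a block only in an alternative. The labels do not say whether an L-GMP and a bulk sample of 1 number came from 1 mouse. The fit with that pairing as a random block had a consensus correlation of 0.53.

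The procedure was tested on simulated data for the L-GMP genotype comparison, with 200 of 12393 genes changed in each of 10 draws. It recovered 7.8 percent of changes of 1 log2 unit, 79.8 percent of 2, 95.4 percent of 3 and 99.0 percent of 5, with 8 false calls per draw. A list shifted by -0.3 was called in 10 of 10 draws. The simulated genes varied independently of each other, with the same spread in all groups. On the arrays the SD of replicate differences was 0.77 and 0.86 in Dnmt1 fl/+ L-GMPs and bulk cells, against 0.39 and 0.55 in controls. The simulation therefore does not show how recovery or list calls behave among correlated genes or groups of unequal spread. The alternatives were the litter and the random block, other normalizations, pseudocounts of 1 and 64, other rules for probe sets, a filter on dim genes, a variance trend, array weights, fits of 4 arrays, leaving out each array, and other thresholds. Leaving out both arrays of a Dnmt1 fl/+ leukaemia, and omitting normalization between arrays, were added after the data were seen.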

Results

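Messenger RNA was measured on 8 Affymetrix mouse arrays, each hybridised with RNA from spleen cells of mice that carried acute myeloid leukaemia driven by the MLL-AF9 fusion. Leukaemias came from bone marrow progenitors of Dnmt1 fl/+ Mx-Cre mice, in which poly(I:C) deletes 1 Dnmt1 allele, or of Dnmt1 fl/fl controls. The sample titles name Cre for the Dnmt1 fl/+ samples only. If the controls lacked it, Cre cannot be told apart from the Dnmt1 dose in any genotype comparison. From each genotype, leukaemic granulocyte-macrophage progenitors (L-GMPs, the population enriched for leukaemia stem cells) and bulk GFP-positive leukaemia cells were sorted, which gave 4 groups of 2 arrays. The series asks what a reduced dose of the maintenance DNA methyltransferase does to gene expression in these cells. Arrays that share a replicate number came from littermates, and the number of arrays limits the precision of every value. Median probe set signals lay between 206 and 234 on the 8 arrays. Unless stated otherwise, each gene value is a log2 difference ± SE with n = 2 arrays per group, on the scale of log2 of the signal plus 16, which understates changes of dim genes. The SE uses a spread per gene pooled over all 4 groups, so it does not measure the spread of the arrays compared.

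Dnmt1 itself was abundant on all arrays, with signals between 2908 and 5915. The log2 difference between Dnmt1 fl/+ and control arrays was -0.25 ± 0.32 in L-GMPs and -0.46 ± 0.32 in bulk cells for 1 probe set, and -0.41 ± 0.41 and -0.78 ± 0.41 for the other. Neither population passed the test for the first probe set (limma adjusted p = 1 and 0.808). Within replicate numbers 1 and 2 that probe set differed by -0.38 and -0.12 in L-GMPs and by -1.02 and 0.10 in bulk cells. The position of the probes relative to the deleted part of the gene was not determined, so these values check neither the deletion nor the labels.

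In L-GMPs, the comparison of Dnmt1 fl/+ with control leukaemias was led by genes of the eosinophil granule. Prg3 fell by 6.11 ± 0.22 on the log2 scale, Prg2, which encodes the major basic protein, fell by 5.91 ± 0.31, and Epx, the eosinophil peroxidase, fell by 4.19 ± 0.39. Hdc, the enzyme that makes histamine, fell by 3.93 ± 0.26, and Akr1c13, an aldo-keto reductase, fell by 3.09 ± 0.24. Both control arrays lay above both Dnmt1 fl/+ arrays for each of these 5 genes. No gene was past the threshold in the other direction.

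**Figure D1:**
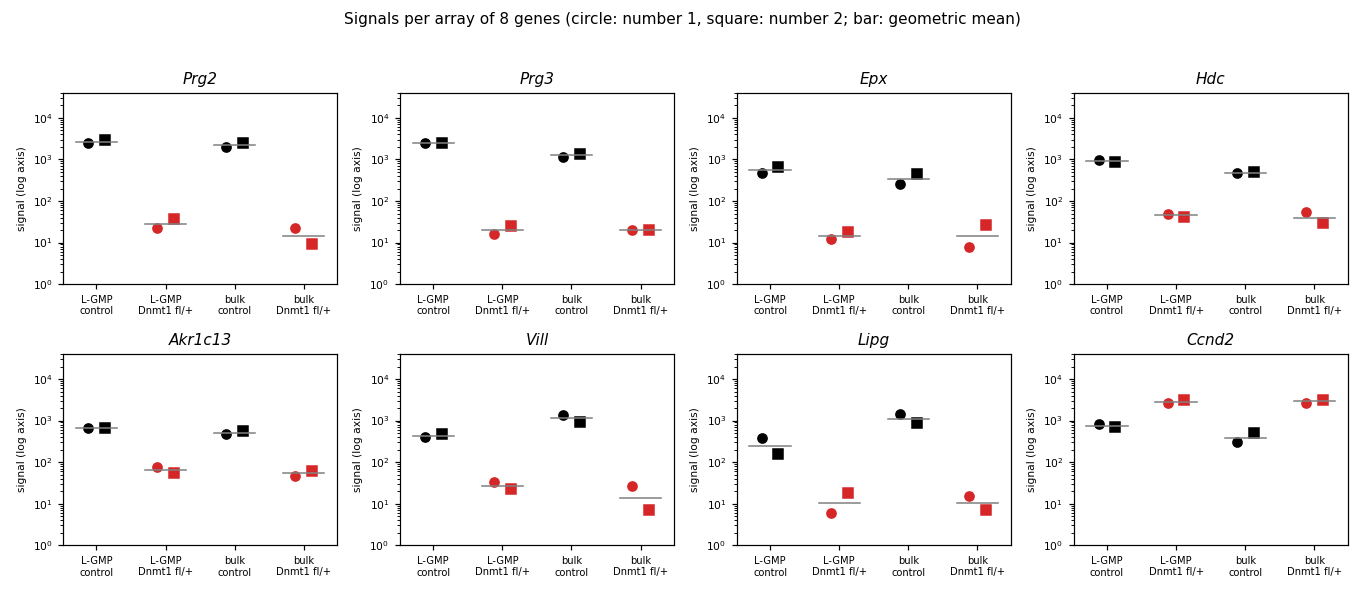
Signals of 8 genes on each of the 8 arrays, by population and genotype, on a log axis in arbitrary signal units. Circles are arrays numbered 1, squares arrays numbered 2, and bars geometric means of 2 arrays. For Prg2, Prg3, Epx, Hdc, Akr1c13 and Vill, both control arrays lie above both Dnmt1 fl/+ arrays in each population.

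The adjusted p-values of the 5 genes were 0.000444 for Prg3, 0.00226 for Prg2, 0.00806 for Hdc, 0.0182 for Akr1c13 and 0.0403 for Epx. Within numbers 1 and 2 the differences were -6.30 and -5.92 for Prg3, -5.99 and -5.82 for Prg2, and -4.09 and -4.28 for Epx. They were -3.91 and -3.95 for Hdc, and -2.88 and -3.30 for Akr1c13. Among 12393 genes, 435 had an unadjusted p under 0.05, where 620 would be expected by chance. Without both arrays of the Dnmt1 fl/+ leukaemia numbered 1, 8 genes passed, of which 3 were among the 5, and without those of number 2, 63 passed, with all 5 among them. The lone Dnmt1 fl/+ array left in each population is then assumed to vary like the other groups. Leaving out either L-GMP control array left 1 gene past the threshold, and leaving out either Dnmt1 fl/+ L-GMP array or either bulk control array left 2.

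Several further genes had large differences in L-GMPs that did not pass. Vill, a villin-like actin-binding protein, was at -3.38 ± 0.35 (adjusted p = 0.0554), and Vcam1, an adhesion molecule, at -2.82 ± 0.30 (adjusted p = 0.0554). On the higher side stood the choline transporter Slc44a1 at 2.39 ± 0.26 (adjusted p = 0.0574, with a dimmer probe set at 0.00 ± 0.49), Trps1 at 2.16 ± 0.28, Tcf7l2 at 2.02 ± 0.31, Selenop at 1.46 ± 0.24, and the D-type cyclins Ccnd2 at 1.89 ± 0.29 and Ccnd1 at 1.73 ± 0.29, with adjusted p between 0.138 and 0.353. Siglecf, a lectin of the eosinophil surface, was chosen after its values were seen and stood at -1.94 ± 0.63 (adjusted p = 1). Targets of the fusion included Hoxa9 at 0.17 ± 0.20, Hoxa10 at 0.16 ± 0.22, Meis1 at 0.38 ± 0.38, Flt3 at 2.31 ± 0.73 and Id2 at 2.71 ± 0.82, none past the threshold. The progenitor receptors Kit and Cd34 differed by -2.24 and -3.83 within number 1 and by 0.42 and 0.23 within number 2. The cell cycle inhibitors Cdkn1a at -0.85 ± 0.78 and Cdkn1b at 0.09 ± 0.49 did not pass either.

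Of 32 gene lists fixed before the data were examined, 6 fell and 1 rose in Dnmt1 fl/+ L-GMPs by camera with a preset correlation of 0.01. Of 22 mast cell, basophil and eosinophil markers, the 4 genes Prg3, Prg2, Epx and Hdc passed over all genes and adjusted over the list alone, all lower. The basophil protease Mcpt8, chosen after its values were seen, went the other way. Its signals were 231 and 260 on control and 811 and 482 on Dnmt1 fl/+ L-GMP arrays. In the list 15 genes were lower and 7 higher. Its mean shift of -0.96 (-1.11 and -0.82 within numbers 1 and 2) came mostly from the 4 genes, with a median of only -0.13 (camera adjusted p = 0.000541). The call was lost at adjusted p = 0.379 with an estimated correlation, and without both arrays of leukaemia 1 (shift -0.78). Granule genes of myeloid progenitors shifted by -0.36 (-0.25 and -0.47 by number), with 16 of 18 lower, among them Nkg7 at -1.79 ± 0.40 and Mpo, myeloperoxidase, at -0.75 ± 0.53 (adjusted p = 0.0171, and adjusted p = 0.689 with an estimated correlation). This call was lost without the L-GMP control array numbered 1 (-0.32), and without the L-GMP array or both arrays of leukaemia 2 (-0.21).

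Cell cycle lists fell in Dnmt1 fl/+ L-GMPs, by unequal amounts in the litters. G2 and M phase genes shifted by -0.38, with 41 of 43 lower, at -0.52 within number 1 and -0.24 within number 2 (adjusted p = 1.54e-06, and adjusted p = 0.724 with an estimated correlation). Examples were the mitotic kinases Plk1 at -0.93 ± 0.44 and Cdk1 at -0.57 ± 0.31. S phase genes shifted by -0.35, with 38 of 40 lower, at -0.67 within number 1 and -0.04 within number 2 (adjusted p = 0.000198, and adjusted p = 0.802 with an estimated correlation). Examples were the replication factor Cdc45 at -0.55 ± 0.28 and the cyclin Ccne1 at -0.79 ± 0.51. Without the L-GMP array or both arrays of the Dnmt1 fl/+ leukaemia numbered 1 the S phase shift was -0.03 and its call was lost. Myeloid maturation lists also differed between the litters, with neutrophil maturation genes at 1.65 within number 1 and -1.50 within number 2, and monocyte and macrophage genes at 0.70 and -0.69, neither called. No member of the cell cycle lists passed over all genes or adjusted over the list alone.

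Cholesterol biosynthesis genes shifted by -0.28 (-0.29 and -0.26 by number), with 15 of 19 lower, among them Fdps at -0.80 ± 0.31 and Ebp at -0.53 ± 0.25 (adjusted p = 0.00353, and adjusted p = 0.488 with an estimated correlation). Oxidative phosphorylation genes shifted by -0.15 (-0.24 and -0.06 by number), with 56 of 64 lower, such as Uqcrc1 at -0.38 ± 0.22 and Cox5a at -0.34 ± 0.21 (adjusted p = 0.000541, and adjusted p = 0.724 with an estimated correlation). Without the L-GMP array or both arrays of leukaemia 1 both calls were lost, at -0.22 for cholesterol and -0.08 for oxidative phosphorylation genes. Immediate early genes were higher by 0.33, but at 1.14 within number 1 and -0.48 within number 2 (adjusted p = 0.0341, 0.0629 with the litter as a block, and adjusted p = 0.802 with an estimated correlation). Within this list Dusp6 was at 2.03 ± 0.43 and Zfp36l1 at 3.01 ± 1.03. Without the L-GMP control array numbered 1 the shift was -0.04, and without both arrays of leukaemia 1 it was -0.10. With an estimated correlation, camera called 0 of the 32 lists in any of the 5 comparisons, and fry called 2 lists in each genotype comparison and 0 in the others.

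No list that bears on DNA methylation or Polycomb was called by camera in L-GMPs. Developmental regulators that carry bivalent chromatin in stem cells had a mean shift of 0.05 (0.04 and 0.06 by number), with 56 of 98 higher (adjusted p = 0.623). Members named by the rule were Irx2 at 1.24 ± 0.44, Hoxb1 at 0.83 ± 0.29 and Nkx2-5 at -0.68 ± 0.24. Germline genes silenced by DNA methylation shifted by 0.08, with 19 of 31 higher, such as Taf7l at 1.11 ± 0.48 and Tex101 at 0.73 ± 0.25 (camera adjusted p = 0.346, fry adjusted p = 0.0131). The bivalent and germline lists lay near background, at mean log2 levels of 5.14 and 5.31 in control L-GMPs, where the median gene lay at 8.06 over all arrays. Taf7l signals, for example, were 7 and 2 on control and 33 and 22 on Dnmt1 fl/+ L-GMP arrays. For these 2 lists neither the shifts nor the missing calls say much about silencing. Imprinted genes shifted by -0.03 (adjusted p = 0.897), Polycomb subunits by 0.09 (adjusted p = 0.462), the DNA methylation machinery by -0.03 (adjusted p = 0.839), and growth suppressors with the CDK inhibitors by 0.10 (adjusted p = 0.605). By number the last 3 lists went opposite ways, at -0.03 and 0.21, -0.17 and 0.12, and 0.32 and -0.13. Within the Polycomb list, Pcgf2 was at -1.16 ± 0.28 and Bmi1 at 0.73 ± 0.23.

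**Figure D2:**
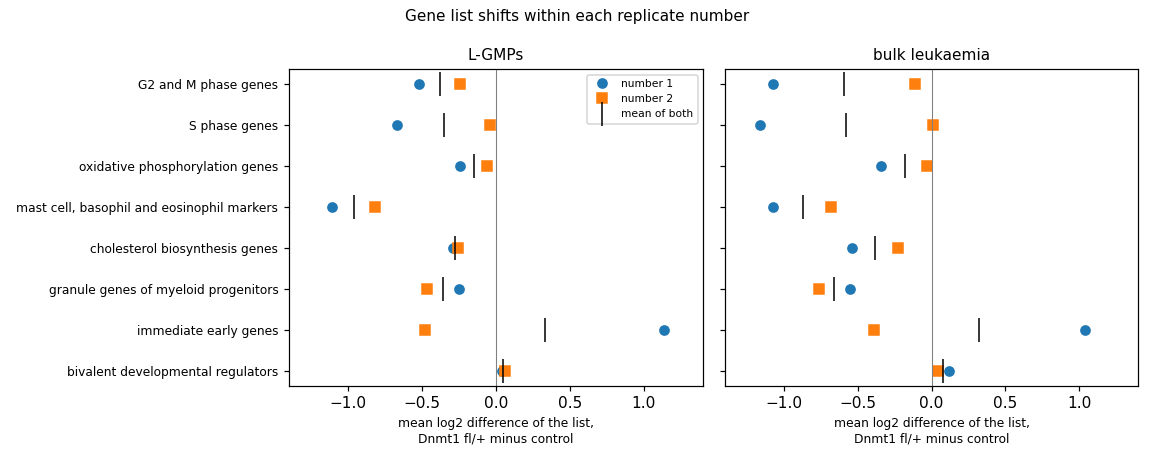
Mean log2 difference of 8 gene lists, Dnmt1 fl/+ minus control, within number 1 (circles), within number 2 (squares) and as the mean of both (bars), in L-GMPs and bulk cells. S phase genes lie at -0.67 and -0.04 in L-GMPs, and at -1.16 and 0.01 in bulk cells.

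In bulk leukaemia cells, 11 genes passed, 4 of which had also passed in L-GMPs. Prg2 fell by 6.19 ± 0.31 on the log2 scale, Prg3 fell by 5.12 ± 0.22, Hdc fell by 3.15 ± 0.26, and Akr1c13 fell by 2.93 ± 0.24. Lipg, the endothelial lipase, fell by 5.36 ± 0.47, Vill fell by 5.21 ± 0.35, the scaffold protein Tanc1 fell by 3.35 ± 0.21, and Vcam1 fell by 3.13 ± 0.30. Ica1 fell by 2.68 ± 0.26 and the cadherin Celsr1 fell by 2.50 ± 0.25. Ccnd2, which drives entry into the cell cycle, was the only gene that rose past the threshold, by 2.88 ± 0.29, and each of its 7 probe sets was higher. The other probe sets of Lipg were at -3.62 ± 0.34 and -1.17 ± 0.42, and without probe sets of possible cross-hybridisation Lipg was at -1.17 and not called. Those of Vcam1 were at -1.67 ± 0.38 and -1.94 ± 0.29, that of Hdc at -2.32 ± 0.24 and that of Ica1 at -1.52 ± 0.29.

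These 11 genes had adjusted p-values from 0.00145 for Prg3 to 0.0328 for Ccnd2. Within numbers 1 and 2 the differences were -5.68 and -6.70 for Prg2, -4.97 and -5.27 for Prg3, -5.50 and -5.22 for Lipg, -5.06 and -5.36 for Vill, and 3.11 and 2.65 for Ccnd2. With the litter as a block, Ica1 (adjusted p = 0.052) and Celsr1 (adjusted p = 0.0568) missed the threshold, while Epx, at -3.47 ± 0.39 and adjusted p = 0.0556 without the block, passed at adjusted p = 0.0131, as did Rgs5, a pericyte gene, at -3.38 ± 0.50 (adjusted p = 0.0376, and 0.175 without the block). Ica1 lay outside the rule for naming genes and is given to complete the count. In all, 848 genes had an unadjusted p under 0.05. The bulk and L-GMP control arrays numbered 1 were over 2-fold apart at 1219 genes. The other pairs of the same number and genotype were so at 352 to 417 genes. Leaving out the bulk control array numbered 2 left 0 genes past the threshold in limma (the lone array is then assumed to vary like the other groups), leaving out number 1 left 1, and leaving out any other single array left 4 to 7. Without both arrays of the Dnmt1 fl/+ leukaemia numbered 1, 52 genes passed, 8 of them among the 11, and without number 2, 81 passed, 9 of them among the 11, again with lone arrays.

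Genes that did not pass in bulk cells included Slc44a1 at 1.95 ± 0.26, Ccnd1 at 1.96 ± 0.29, Tcf7l2 at 2.06 ± 0.31, Trps1 at 1.75 ± 0.28 and Spred1, an inhibitor of Ras signalling, at 1.42 ± 0.24, with adjusted p between 0.11 and 0.26. Flt3 was at 3.14 ± 0.73, Siglecf at -2.42 ± 0.63, Hoxa9 at 0.04 ± 0.20 and Meis1 at 0.06 ± 0.38. Kit and Cd34 differed by -2.97 and -4.69 within number 1 and by 0.02 and 0.77 within number 2.

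Camera called 6 lists lower and 0 higher in bulk cells. G2 and M phase genes shifted by -0.59, with 42 of 43 lower, at -1.07 within number 1 and -0.11 within number 2 (adjusted p = 2.64e-09, and adjusted p = 0.79 with an estimated correlation). S phase genes shifted by -0.58, with 38 of 40 lower, at -1.16 and 0.01 (adjusted p = 6.46e-07, and adjusted p = 0.843 with an estimated correlation). Without the bulk array or both arrays of leukaemia 1 the shifts were -0.10 and 0.02 and neither was called. Granule genes of myeloid progenitors shifted by -0.66 (-0.55 and -0.76 by number), with 17 of 18 lower (adjusted p = 0.000852, and adjusted p = 0.382 with an estimated correlation). Nkg7, at -3.29 ± 0.40, passed adjusted over the list alone and not over all genes, and Elane, neutrophil elastase, was at -1.29 ± 0.76. The granule call was lost without the bulk array or both arrays of leukaemia 2 (-0.50).

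Mast cell, basophil and eosinophil markers shifted by -0.87 (-1.07 and -0.68 by number) in bulk cells, at a median of only -0.14 and with 9 of 22 higher. Among them 3 were past the threshold over all genes, and 5 lower and 1 higher adjusted over the list alone (list adjusted p = 0.0249, and adjusted p = 0.382 with an estimated correlation). Cholesterol biosynthesis genes shifted by -0.38 (-0.54 and -0.23, adjusted p = 0.00281) and oxidative phosphorylation genes by -0.18 (-0.34 and -0.03, adjusted p = 0.00191), at adjusted p = 0.382 and adjusted p = 0.838 with an estimated correlation. These 3 calls were lost without the bulk array or both arrays of leukaemia 1, at -0.65, -0.27 and -0.09, and those of mast cell and cholesterol lists also without the bulk control array numbered 2 (-0.84 and -0.42). Bivalent developmental regulators shifted by 0.08, with 58 of 98 higher, such as Tbx4 at 1.18 ± 0.25 and Irx2 at 1.72 ± 0.44, against Lhx2 at -1.42 ± 0.37 and Gbx2 at -0.92 ± 0.26 (adjusted p = 0.366). Germline genes shifted by 0.07 (camera adjusted p = 0.266, fry adjusted p = 0.0252). The bivalent and germline lists lay near background here too, at mean log2 levels of 5.13 and 5.31 in bulk controls.

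The genotype differences of L-GMPs and bulk cells were compared directly by an interaction. Prg2, Prg3, Hdc and Akr1c13 were past the threshold in both populations, all lower. All 11 genes called in bulk cells differed in the same direction in L-GMPs at an unadjusted p under 0.05, including Lipg at -3.22 ± 0.47 and Tanc1 at -2.06 ± 0.21, both given there after their values were seen. Across 12393 genes, which are not independent replicates, the log2 differences of both populations had a Pearson r of 0.57 and a Spearman rho of 0.43. The labels leave open whether the arrays of both populations came from the same leukaemias. The correlation of 0.8 between populations within Dnmt1 fl/+ points that way for this genotype. In that case the agreement between populations is not independent evidence of a genotype effect.

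The interaction called 0 genes by limma, and 0 genes with the litter as a block. At an unadjusted p under 0.05 there were 223 genes, where 620 would be expected by chance. The fit does not pair arrays of the same number and genotype, so the gap between the Dnmt1 fl/+ leukaemias adds to its error. Genes named by the rule were Ing4 at -1.34 ± 0.28, Tanc1 at 1.29 ± 0.30, Hebp1 at 1.49 ± 0.40 and Vill at 1.83 ± 0.50, all at adjusted p = 1. Prg3, named as a member of its list, was at -0.99 ± 0.32 (adjusted p = 1), with all Dnmt1 fl/+ signals between 16 and 25, so this value repeats the difference between control populations. Camera called 0 lists (smallest adjusted p = 0.256 with the preset correlation and 0.881 with an estimated one). Neutrophil maturation genes had a mean of 0.48 (adjusted p = 0.416). Camera did call lists when a single Dnmt1 fl/+ array was left out. Such a fit leaves 1 leukaemia in 1 population and both in the other. It thereby mixes the gap between the leukaemias into the interaction, and its calls are no evidence of an interaction.

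The comparison of L-GMPs with bulk cells within the controls asks how the progenitor fraction differs from the whole leukaemia. Myeloid maturation lists fell in L-GMPs by camera with the preset correlation, and none was called with an estimated one. Neutrophil maturation genes shifted by -1.34, with 31 of 33 lower (-1.53 and -1.15 by number, adjusted p = 8.87e-06, and adjusted p = 0.709 with an estimated correlation), among them lactoferrin, Ltf, at -3.95 ± 1.58 and Adam8 at -2.06 ± 0.80. Monocyte and macrophage genes shifted by -0.78, with 35 of 36 lower (-0.90 and -0.65 by number, adjusted p = 9.45e-11, and adjusted p = 0.493 with an estimated correlation), such as Ccr2 at -0.94 ± 0.23 and Ms4a6d at -1.84 ± 0.46. Dendritic cell and MHC class II genes shifted by -0.50 (-0.49 and -0.51 by number, adjusted p = 0.00122, and adjusted p = 0.26 with an estimated correlation), with Cd209a at -2.43 ± 0.40, Cd74 at -1.86 ± 0.47 and H2-Aa at -2.49 ± 0.47.

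Interferon-stimulated genes also fell, by 0.38 on the log2 scale (-0.40 and -0.36 by number), with Irf7 at -0.96 ± 0.25 and Ifitm3 at -2.74 ± 0.86 (adjusted p = 0.000209, and adjusted p = 0.239 with an estimated correlation). Inflammatory genes shifted by -0.52 (-0.68 and -0.37, adjusted p = 7.6e-05), with Cd40 at -1.94 ± 0.58, and immediate early genes by -0.36 (-0.53 and -0.19, adjusted p = 0.0357, and 0.0688 with the litter as a block), at adjusted p = 0.493 and adjusted p = 0.72 with an estimated correlation.

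Lists that rose in control L-GMPs were G2 and M phase genes (0.30, 41 of 43 higher, adjusted p = 0.000111), Myc targets with ribosome biogenesis (0.24, 41 of 49 higher, adjusted p = 0.00064) and mast cell, basophil and eosinophil markers (0.25, 16 of 22 higher, adjusted p = 0.0332). By number the shifts were 0.32 and 0.29, 0.22 and 0.27, and 0.24 and 0.26. These had adjusted p = 0.709, 0.72 and 0.469 with an estimated correlation. Of the 9 lists called, 3 were left without the bulk control array numbered 2. The mast cell list was also lost without bulk control array 1 (0.22) or L-GMP control array 2 (0.21), and immediate early genes without L-GMP control array 1 (0.02). S phase genes were at 0.14 (adjusted p = 0.224) and were not called. Examples were Cdk1 at 0.63 ± 0.31, Kif11 at 0.62 ± 0.31, Wdr12 at 0.74 ± 0.31, Polr1b at 0.96 ± 0.50, Hdc at 0.91 ± 0.26, Epx at 0.67 ± 0.39 and Prg3 at 0.99 ± 0.22. The gate markers Kit and Cd34 were at 0.98 ± 1.06 and 0.36 ± 1.94. These SEs pool all groups, and the Cd34 signals of the controls themselves were 1770 and 1864 in L-GMPs, and 1264 and 1580 in bulk cells. No single gene passed in limma, with or without the litter as a block (0 genes, smallest adjusted p = 0.995). At an unadjusted p under 0.05 there were 456, where 620 would be expected by chance. Genes that the naming rule took were Ifi27l2a at -2.90 ± 0.49, Sdc1 at -2.32 ± 0.41, Nrp1 at -2.98 ± 0.57, Mfsd6 at -1.89 ± 0.37 and Capn2 at -1.52 ± 0.31.

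Within Dnmt1 fl/+ leukaemias, camera called 4 lists higher and 7 lower in L-GMPs than in bulk cells. G2 and M phase genes rose by 0.51, with 43 of 43 higher (0.86 and 0.16 by number), for example Aurka at 0.66 ± 0.27 and Ect2 at 0.93 ± 0.43. S phase genes rose by 0.37, with 38 of 40 higher (0.64 and 0.09 by number), and the members E2f8, Mcm10, Rrm2 and Tk1 stood at 0.35 ± 0.24, 0.92 ± 0.64, 0.53 ± 0.36 and 0.54 ± 0.37. Granule genes rose by 0.35 (0.34 and 0.36 by number), and Nkg7, at 1.88 ± 0.40, passed adjusted over the list alone. Myc targets with ribosome biogenesis rose by 0.19 (0.25 and 0.14 by number), with Wdr12 at 0.43 ± 0.31. The adjusted p-values of these 4 lists were 1.59e-15, 3.56e-06, 0.000779 and 0.000624, and with an estimated correlation none was called (adjusted p = 0.483, 0.836, 0.263 and 0.851).

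The 7 lists that fell in Dnmt1 fl/+ L-GMPs included monocyte and macrophage genes at -0.55 (-0.26 and -0.84 by number), with Itgax at -0.75 ± 0.28 and Cx3cr1 at -0.96 ± 0.38, and neutrophil maturation genes at -0.86 (-0.69 and -1.03), with Mmp8 at -2.18 ± 1.44. Inflammatory genes at -0.34 (-0.37 and -0.31), with Cxcl1 at -1.15 ± 0.49, immediate early genes at -0.35 (-0.43 and -0.27), with Fosl1 at -0.83 ± 0.29, and interferon-stimulated genes at -0.18 (-0.11 and -0.25) were also lower. B cell markers fell by 0.23 on the log2 scale (-0.16 and -0.30), and T and NK cell markers fell by 0.16 (-0.19 and -0.14), with Cd8a at -0.72 ± 0.28. Both lists were dim. In L-GMPs and bulk cells their mean log2 levels were 6.22 and 6.45 (B cell) and 5.83 and 5.99 (T and NK). The median gene lay at 8.06, so these 2 shifts say little about lymphoid transcripts. Adjusted p-values of all 11 lists lay between 1.59e-15 and 0.0122, and the smallest adjusted p = 0.263 with an estimated correlation.

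No single gene passed in this comparison by limma, with or without the litter as a block (0 genes). At an unadjusted p under 0.05 there were 216, where 620 would be expected by chance. The main fit does not pair arrays of the same number and genotype, so the gap between the leukaemias adds to its error. That makes the test conservative. The litter block is shared by both genotypes and does not remove this gap. With the pairing as a random block 0 genes passed as well. Genes that the naming rule took were Nkg7, Ptch1 at 0.85 ± 0.23, H2-DMb2 at -0.89 ± 0.22, Capn2 at -1.15 ± 0.31 and Evi2a at -0.84 ± 0.22. Others named were Hlf, a stem cell transcription factor, at 1.84 ± 0.49, H2-Aa at -1.60 ± 0.47, Kit at 1.54 ± 1.06 and Cd34 at 0.52 ± 1.94. Leaving out the bulk array of leukaemia 1 turned the shifts of S phase genes to -0.23, neutrophil genes to 0.40, immediate early genes to 0.16 and Myc targets to -0.15, and left G2 and M phase genes at 0.02 and inflammatory genes at -0.04, with 6 lists called. Leaving out the L-GMP array of leukaemia 2 turned neutrophil genes to 0.57, immediate early genes to 0.08 and Myc targets to -0.09, and left monocyte genes at 0.02, S phase genes at 0.04 and inflammatory genes at -0.07, with 3 lists called. Either fit sets 2 arrays of one population against 1 of the other and so mixes the gap between the leukaemias into the shift, while within each number all of these lists kept their direction. With both arrays of a leukaemia left out, calls were still lost, those of S phase genes (0.09), immediate early genes (-0.27), Myc targets (0.14) and T and NK cell markers (-0.14) without leukaemia 1, and those of B cell markers (-0.16), interferon-stimulated genes (-0.11) and T and NK cell markers (-0.19) without leukaemia 2. Granule genes lost their call without L-GMP array 1 (0.20) or bulk array 2 (0.19), T and NK cell markers without the same arrays (0.02 and -0.01), B cell markers without L-GMP array 2 (-0.20) or bulk array 2 (-0.19), and interferon-stimulated genes without any 1 of the 4 arrays (-0.24 to -0.12).

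The arrays of the Dnmt1 fl/+ leukaemias stood far apart from each other in both populations. Differences of over 4-fold in one direction in both L-GMPs and bulk cells were found for 238 genes, against 5 between the controls. Control arrays carried Xist and Y-linked transcripts together, as a mixture of male and female cells would. If they were mixtures, they are not a like baseline for single leukaemias. Leukaemia 1 had higher signals of the neutrophil genes Mmp9 (3230 against 27.5 in L-GMPs), Lcn2 (3880 against 59.5) and Ngp (8070 against 256). Leukaemia 2 had higher Cd34 (2190 against 110), Kit (1570 against 297), Sox4 (2590 against 86.0), Satb1 (3510 against 371) and Il7r (1910 against 66.7). The L-GMP gate selects for CD34 and c-Kit protein, yet both transcripts were lower in the L-GMPs of leukaemia 1 than in control L-GMPs and control bulk cells. Control L-GMP signals were 1770 and 1860 for Cd34, and 1470 and 1180 for Kit. All of these genes were chosen after their values were seen, and no test was run between single leukaemias.

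**Figure D3:**
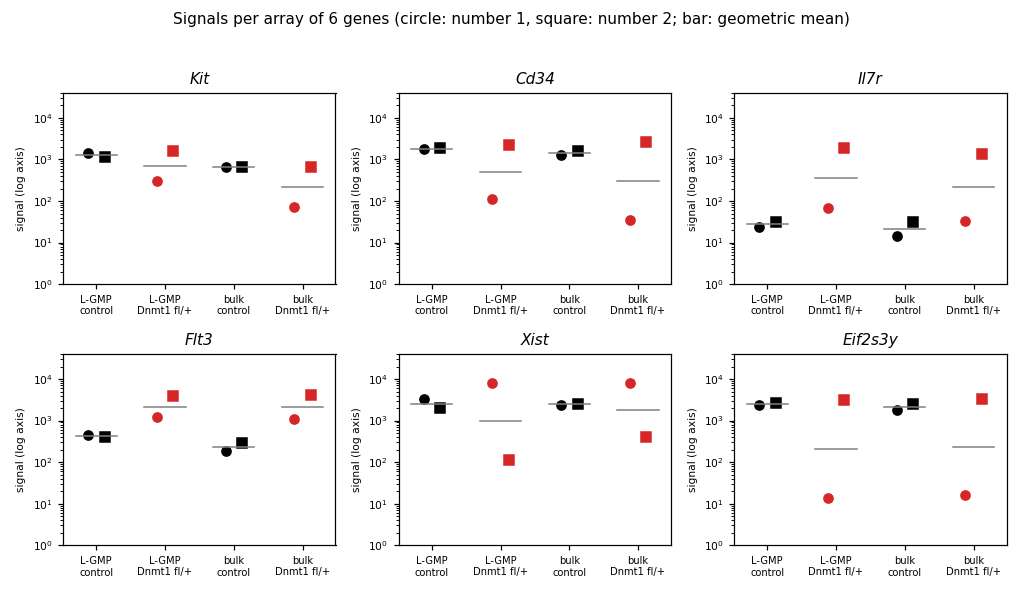
Signals of 6 genes on each of the 8 arrays, by population and genotype, on a log axis in arbitrary signal units, with circles for number 1, squares for number 2 and bars for geometric means of 2 arrays. Cd34 lies at 110 and 2190 on the Dnmt1 fl/+ L-GMP arrays, against 1770 and 1860 on the control arrays.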

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

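All tests of explanations in this part were chosen after the results they bear on were seen. Outside the gene-level comparisons, 2246 probe sets matched several genes or none, and 2 of them passed the limma test for genotype in L-GMPs and 1 in bulk cells. A probe set past the threshold in both was at -2.41 ± 0.24 in Dnmt1 fl/+ L-GMPs and at -2.89 ± 0.24 in bulk cells (limma adjusted p = 0.046 and 0.0304). The other was at -4.26 ± 0.39 in L-GMPs (limma adjusted p = 0.046). They stand out because the gene-level comparisons do not use such probe sets, and no gene name is given for either.

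The eosinophil granule genes Prg2, Prg3 and Epx, with Hdc, had a mean log2 difference of -4.76 on Dnmt1 fl/+ arrays, from control L-GMP signals of 2428 and 2925 for Prg2 and 462 and 644 for Epx. The values argue against mature eosinophils that the L-GMP gate (lineage-negative, Kit-positive) removes, since in controls none of the 4 genes was lower in L-GMPs than in bulk cells. The differences ran from 0.26 for Prg2 to 0.99 for Prg3, with a mean of 0.71. The SE over genes of 0.16 treats genes that vary together as replicates and does not measure the spread between the 2 arrays of a population. The values also argue against the sex of the leukaemia cells, since the female and the male Dnmt1 fl/+ leukaemia differed by a mean of only -0.05 over these genes. What stays open is the genotype itself, including Cre, which only the titles of Dnmt1 fl/+ samples name. A difference between founding cells or donors that happens to run with genotype in 2 leukaemias against 2 also stays open. So do cells of the eosinophil lineage that fall within the gate. A genotype effect is therefore a hypothesis that further leukaemias could test.

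The Dnmt1 fl/+ leukaemias stood far apart, with 238 genes over 4-fold apart in both populations (5 between controls). The controls are not a like baseline if they were mixtures of cells, which their sex-linked transcripts leave possible. Technical measures did split by number, among them 3 hybridisation controls and the 3' to 5' signal ratio of Gapdh. That ratio was 2.32 to 2.72 on arrays numbered 1 and 2.98 to 3.09 on arrays numbered 2, while the ratio of beta-actin did not split. As the source of the gap, a batch that acts alike on controls and Dnmt1 fl/+ arrays is argued against. The differences between numbers in controls correlated with those in Dnmt1 fl/+ arrays at no more than 0.15 across genes. Leukaemias that arrested at different stages may also account for the gap, and no biological explanation was tested, as no label separates the pair.

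Control arrays carried Xist and Y-linked transcripts together, with Xist signals between 1967 and 3227, against 8145 and 7990 in one Dnmt1 fl/+ leukaemia and 114 and 393 in the other. As shares of those leukaemias, the Xist share plus the mean share of the measured Y-linked genes was 0.972 on average (0.861 to 1.16 on the 4 arrays), near the 1 that a mixture of male and female cells would give. Cells that each carry both at full level would give about 2, which the same mean of 0.972 argues against, and background of the Xist probe set is argued against by a lowest control signal 5.00 times that of the male leukaemia. A mixture is therefore a candidate explanation, with pooled donors, or host cells that passed the sort for GFP, which should remove them, as possible sources that these data do not separate.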

How the results depend on the processing

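Leaving out both arrays of a Dnmt1 fl/+ leukaemia, and omitting normalization between arrays, were chosen after the data were seen, and all other alternatives before. The causes of the changes below were not tested, except that settings with fewer genes or arrays test less. Where a group keeps 1 array, that array is assumed to vary like the other groups.

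With the replicate block (the litter), 5 genes passed in L-GMPs, the same 5, and 13 in bulk cells, 9 of them shared. In bulk cells Celsr1 (0.0302 to 0.371 over all alternatives) and Ica1 (0.0285 to 0.359) lost their calls with the block, and Epx (0.0131 to 0.359) and Rgs5 (0.0376 to 0.812) gained one, each as adjusted p. The immediate early list lost its call in L-GMPs (2.45e-05 to 0.989) and between populations in controls (4.86e-05 to 0.994), and Myc targets gained one in L-GMPs at 0.0452. The block changed no other call of a gene named here or of a list. In L-GMPs the count of 5 genes became 1 with only genes above the median signal, with only the 4 arrays compared, and with pseudocount 1. It became 12 with array weights, 11 at adjusted p under 0.10, and 382 at unadjusted p under 0.05 and 1.5-fold. Without leukaemia 1 it was 8 and without leukaemia 2 it was 63. Leaving out single arrays gave 1 to 6. In bulk cells the 11 genes became 1 above the median signal, 6 with array weights, 2 with 4 arrays, 3 with pseudocount 1 and 781 at unadjusted p under 0.05 and 1.5-fold. They became 52 without leukaemia 1, 81 without leukaemia 2, and 0 to 7 without single arrays. The other thresholds at unadjusted p under 0.05 and 1.5-fold gave 223 genes for the interaction, and 423 and 188 between populations in control and Dnmt1 fl/+. These 3 counts were 0 in limma in every other alternative run.

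Prg3 stayed past the threshold in 22 of 22 alternatives in L-GMPs and 21 of 22 in bulk cells, and Prg2 in 19 and 21 of 23. Epx in L-GMPs was kept in 12 of 22, Ccnd2 in bulk cells in 8 of 23 and Celsr1 in 7 of 22. Lipg in bulk cells was kept in 12 of 22, from -6.56 to -1.17, the last without probe sets of possible cross-hybridisation. The Dnmt1 difference kept its direction, from -0.44 to -0.05 in L-GMPs and from -0.86 to -0.05 in bulk cells. With an estimated correlation 0 lists were called in each comparison. Lists called in L-GMPs were 4 without leukaemia 1, only 2 of the 7 among them (G2 and M phase and granule genes), and 5 to 10 without single arrays. In bulk cells they were 4 to 8 without single arrays, and 5 without leukaemia 1, of which only the granule list was among the 6. Without leukaemia 2 the granule list lost its call in both, at -0.21 and -0.50. For the interaction, leaving out a single Dnmt1 fl/+ array mixes in the gap between the leukaemias. Without leukaemia 2, or without such an array, lists were called. Between populations they were 3 to 10 in controls and 3 to 11 in Dnmt1 fl/+.

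Over all alternatives, values of named genes kept direction and call 2587 times, lost a call 121 times, gained one 30 times and turned direction 25 times. Called lists did so 416, 98, 0 and 12 times. Without leukaemia 1, L-GMP genotype differences were 0.27 for Cd34, 0.26 for Kit, 0.01 for Cdkn1a, -0.50 for Cdkn1b and -0.10 for immediate early genes, and without single arrays these ranged from -3.87 to 0.27, -2.09 to 0.26, -1.71 to 0.01, -0.50 to 0.68 and -0.10 to 0.76. In bulk cells they were 0.93 for Cd34, 0.03 for Kit, -0.05 for Hoxa9, -0.48 for Meis1 and 0.02 for S phase genes, with ranges of -4.84 to 0.93, -2.98 to 0.03, -0.05 to 0.13, -0.48 to 0.60 and -1.17 to 0.02. Meis1 in bulk cells was also -0.07 without normalization between arrays. Between populations in Dnmt1 fl/+, Cd34 was -0.30 without leukaemia 1. Without single arrays it ranged from -2.37 to 3.40, Mcm10 from -0.09 to 1.94, Rrm2 from -0.01 to 1.07 and Tk1 from -0.04 to 1.13. The lists ranged from -2.29 to 0.57 for neutrophil maturation, -0.23 to 0.96 for S phase, -0.86 to 0.16 for immediate early and -0.15 to 0.54 for Myc targets. Leaving out the L-GMP array of leukaemia 2 or the bulk array of leukaemia 1 turned the neutrophil, immediate early and Myc lists there, in fits that set both leukaemias of one population against 1 of the other. The means of immediate early genes between populations in controls, and of monocyte genes and T and NK cell markers in Dnmt1 fl/+, reached 0.02 without a single array, with the test still in the first direction. Signals near background limit dim genes, and 2218 genes had a mean signal under the pseudocount.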

Other observations

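The camera tests in this part were fixed before the data were examined, and the comparison of single leukaemias was chosen after. Lists of markers of other spleen cell types were not called for genotype in L-GMPs, though Vcam1, at -2.82 ± 0.30, passed adjusted over the resident splenic macrophage list alone. Erythroid markers had a mean shift of 0.18 (camera adjusted p = 0.346), B cell markers of 0.09 (0.839), T and NK cell markers of 0.04 (0.839), megakaryocyte and platelet markers of 0.06 (0.881), resident splenic macrophage markers of 0.02 (0.765) and stromal and endothelial markers of -0.07 (0.839). The stem and progenitor list shifted by -0.16 (0.97), MLL-AF9 targets by 0.13 (0.498), neutrophil maturation genes by 0.08 (0.839), monocyte and macrophage genes by 0.00 (0.913) and dendritic cell genes by 0.17 (0.346). Interferon-stimulated genes shifted by 0.10 (0.477), inflammatory genes by 0.06 (0.881), p53 targets by 0.07 (0.566), apoptosis regulators by 0.11 (0.346), heat shock and unfolded protein response genes by -0.09 (0.34), Myc targets by -0.14 (0.0733), glycolysis and hypoxia genes by -0.05 (0.839) and ribosomal proteins by 0.04 (0.605). Several of these means join opposite shifts within numbers 1 and 2, at 1.65 and -1.50 for neutrophil, 0.70 and -0.69 for monocyte, 0.52 and -0.40 for inflammatory, -0.52 and 0.20 for stem and progenitor, -0.40 and 0.12 for Myc target and 0.26 and -0.21 for resident macrophage lists. Mean and test differed in sign for imprinted genes, neutrophil maturation genes and T and NK cell markers, and mean and median for stem and progenitor, neutrophil, megakaryocyte, stromal and inflammatory lists.

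In bulk cells, MLL-AF9 targets shifted by 0.23 (camera adjusted p = 0.131), immediate early genes by 0.32 (0.0936), neutrophil maturation genes by -0.40 (0.266), monocyte and macrophage genes by -0.22 (0.266) and the stem and progenitor list by -0.22 (0.79). Within numbers 1 and 2 these were 0.29 and 0.17, 1.04 and -0.39, 0.81 and -1.62, 0.06 and -0.50, and -0.60 and 0.16. The DNA methylation machinery shifted by -0.09 (0.79), Polycomb subunits by -0.12 (0.774), imprinted genes by -0.06 (0.79) and growth suppressors with the CDK inhibitors by -0.05 (0.912), of which the last 2 had a test in the other direction. By number these were -0.42 and 0.23, -0.42 and 0.19, 0.10 and -0.22, and 0.13 and -0.23. Stromal and endothelial markers shifted by -0.21 (0.79), with Rgs5 past the threshold adjusted over the list alone, and the resident splenic macrophage markers by -0.10 (0.809, with the test in the other direction), among them Vcam1, which passed over all genes.

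Lists also differed between the Dnmt1 fl/+ leukaemias, as described values without a test, and the genes given here were chosen after their values were seen. Neutrophil maturation genes were higher in leukaemia 1 by a mean of 2.87 in L-GMPs and 2.53 in bulk cells, with 30 of 33 higher in both, where the control arrays numbered 1 and 2 differed by -0.28 and 0.10. Myc targets with ribosome biogenesis were at -0.57 and -0.68, with 47 of 49 lower in both, and S phase genes at -0.65 and -1.19, with 38 of 40 lower in both. Mycn, a Myc family transcription factor, had signals of 16300 and 16100 in leukaemia 1, against 5710 and 6450 in leukaemia 2. Il7r, whose protein the L-GMP gate excludes, had signals of 1910 in the L-GMPs and 1390 in the bulk cells of leukaemia 2, against 24.3 and 31.2 in control L-GMPs. The lymphoid gene Rag2, and Tcf4, which the fixed lists place with dendritic cell genes, were at 750 and 5590 in the L-GMPs of leukaemia 2. In those of leukaemia 1 they were at 45.2 and 336. Control L-GMPs lay between, at 157 and 129 for Rag2 and at 1220 and 1340 for Tcf4. The fixed list of B cell markers differed by only 0.06 and -0.08 between the leukaemias in L-GMPs and bulk cells, and T and NK cell markers by -0.35 and -0.30. Siglecf was at 2866 and 3006 on control L-GMP arrays and at 420 and 1334 on Dnmt1 fl/+ ones, while the eosinophil receptors Ccr3 and Il5ra stayed at or below 27 on all 8 arrays.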
